A study of Mus musculus with 2 samples.

How the data were processed

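H3K4me2 was measured by ChIP-seq in 2 biological replicates of mouse kidney at embryonic day 14.5, per the labels each from pooled male and female embryos. The labels give a size range of 300 to 500 for the libraries. The replicates were separate biological samples of 1 group, so no test between groups was possible and the spread between replicates is given as the SD of 2 values or as both values.

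4 peak lists were analysed. Per the labels and the text descriptions deposited with the lists, 2 lists were called on each replicate alone, 1 on the alignments of both replicates together (the pooled list) and 1 was made from the pooled and replicate lists (the replicated list), all on the mm10 assembly in narrowPeak format with the same control files as input. The aligner, the peak caller, their versions and their filters are not given in the sources used here. The enrichment per peak is the authors' value, read as a linear ratio over control because it exceeds 1 for every peak. The −log10 p and −log10 q per peak are the authors' deposited values, and the lowest −log10 p in a list is between 2.00 and 2.08. The deposited display score per peak was not used for any result, nor was the deposited summit offset. The peak scores and enrichments are the authors' own values and were used to describe, rank and filter peaks, and to compare the ranks of overlapping peaks. The depth per sample is unknown, so the enrichment values are not corrected for it, and a weakly marked region can be missed in a shallower library. Intervals on shares of peaks cover counting error only.

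Peaks were compared with the GRCm38 genome sequence, which is the same assembly, and with the GENCODE M21 annotation, which gave 21938 protein-coding genes on the assembled chromosomes with 93513 distinct TSSs. Coordinates are 1-based on mm10. Overlap meant at least 1 bp, and the chance level came from 100 shuffles of peak positions within chromosomes. Peak centres were assigned to promoter (within 1 kb of a coding TSS), exon, intron or intergenic sequence, in that order. A gene was called marked when a replicated peak lay within 1 kb of any of its TSSs, and its enrichment is that of the strongest such peak. Neighbouring Hox genes can share 1 wide peak and then have the same enrichment. Peaks were not assigned to 1 gene each, so a peak at a neighbouring gene's promoter can also mark a gene. Breadth was the largest number of covered bases within 5 kb over the TSSs of a gene. Distal peaks had their centre over 2.5 kb from every coding TSS and were counted for a gene within 50 kb of any of its TSSs.

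20 gene lists were tested: nephron progenitors, ureteric bud and collecting duct, early nephron, podocytes, proximal tubule, loop of Henle and distal tubule, renal stroma, endothelium, leukocytes, erythroid cells, neural crest and neurons, adrenal cortex and gonad, 4 lists of other tissues (brain and eye; liver, pancreas, gut and lung; muscle, heart and skin; pluripotency and germ line), housekeeping genes, Hox genes, signalling ligands and olfactory receptors. All 354 symbols written for the first 19 lists matched the annotation, and they stand for 341 distinct genes. Marked shares were tested with 2-sided Fisher's exact tests. Breadth among marked genes and distal peaks were tested with 2-sided permutation tests of 100000 random lists (10000 for olfactory receptor genes in the distal and matched tests). P-values were adjusted by the Benjamini-Hochberg method over the 20 lists. Matched tests drew random genes from 10 bins of promoter CpG count within 500 bp of the gene 5' end, or from 5 bins of gene density. Motif sites of 19 consensus sequences were counted on both strands in distal peaks and in intervals of the same length 5 kb away on either side, outside every list's peaks. Flanks were standardised to the peaks in GC bins of 2%, and intervals came from 1000 bootstrap samples of chromosomes.

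The lists, motifs, main tests and the alternatives were chosen before the data were examined, except where the text says otherwise. The exact rules for breadth and distal distance were fixed before any value was seen. The alternatives were a stricter q, reciprocal overlap, equal numbers of peaks, other windows, joining distances and backgrounds, the pooled list, and each replicate alone. The genes named were set by rule: for each list the 3 members with the most covered bases within 5 kb, the 2 with the fewest, and the members lacking a peak where they were 4 or fewer; the genes in the 10 widest domains; the 10 genes with the most distal peaks; up to 10 members marked in 1 replicate only; and the 3 strongest peaks of each replicate alone and the 5 strongest replicated peaks. The other Hox genes, Mael, Tmem52b, Vil1, and all genes in the gene family and noncoding results were named after their values were seen.

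The programs were written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, with samtools 1.23.1 for sequence indexing. They were tested on simulated data. Among 200 random lists of 20 genes with no effect, 4.5% passed an unadjusted p of 0.05 for promoter marking, 4.5% for breadth and 2% for distal peaks; with planted effects 98.5%, 87.5% and 97% passed. Overlaps checked by brute force gave 0 mismatches over 915 comparisons, and all 7600 planted motif sites were found.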

Results

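Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 dimethylated at lysine 4 (H3K4me2) in the kidney of mouse embryos at embryonic day 14.5. H3K4me2 is a modification found at promoters and enhancers that are active or poised. At this stage nephron progenitors, the branching ureteric bud, early nephrons, stroma and vessels lie side by side in the organ. The series held 1 group of 2 biological replicates, each made from tissue pooled from male and female embryos, so the design allowed comparisons between replicates, between peak lists and between sets of genes, and no comparison between conditions. Replicate 1 had 44043 peaks covering 40.1 Mb and replicate 2 had 51774 peaks covering 47.5 Mb. The pooled list, called on both replicates together, had 43075 peaks, and the replicated list had 33553 peaks covering 44.6 Mb, or 1.68% of the ungapped genome. The number of reads behind each list is unknown, because the files hold called peaks and no read counts.

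Most marked regions were found in both replicates. Of the replicate 1 peaks, 82.8% (95% exact binomial interval 82.4% to 83.1%, 44043 peaks) overlapped a replicate 2 peak by at least 1 bp, and 65.7% (65.3% to 66.1%, 51774 peaks) of the replicate 2 peaks overlapped a replicate 1 peak. Peaks of the same lengths placed at random within their chromosomes overlapped in 3.48% and 3.01% of cases, as means of 100 shuffles. Shared peaks were strong, wide and close to genes: in replicate 1 they had a median enrichment over control of 8.01 and a median width of 794 bp, and 53.1% lay within 1 kb of a transcription start site (TSS) of a protein-coding gene. Peaks found in replicate 1 alone had a median enrichment of 3.07 and a width of 213 bp, and 9.78% lay within 1 kb of a TSS. For replicate 2, shared peaks had a median enrichment of 14.7 and a width of 989 bp, against 3.56 and 226 bp for the peaks found there alone. Ranked by the deposited −log10 p, 100% of the peaks were shared in the strongest decile of each list. In the weakest decile 40.6% were shared in replicate 1 and 16.7% in replicate 2. In bases, 36.5 Mb were marked in both lists, which was 91.0% of the replicate 1 bases and 76.9% of the replicate 2 bases.

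**Figure D1:**
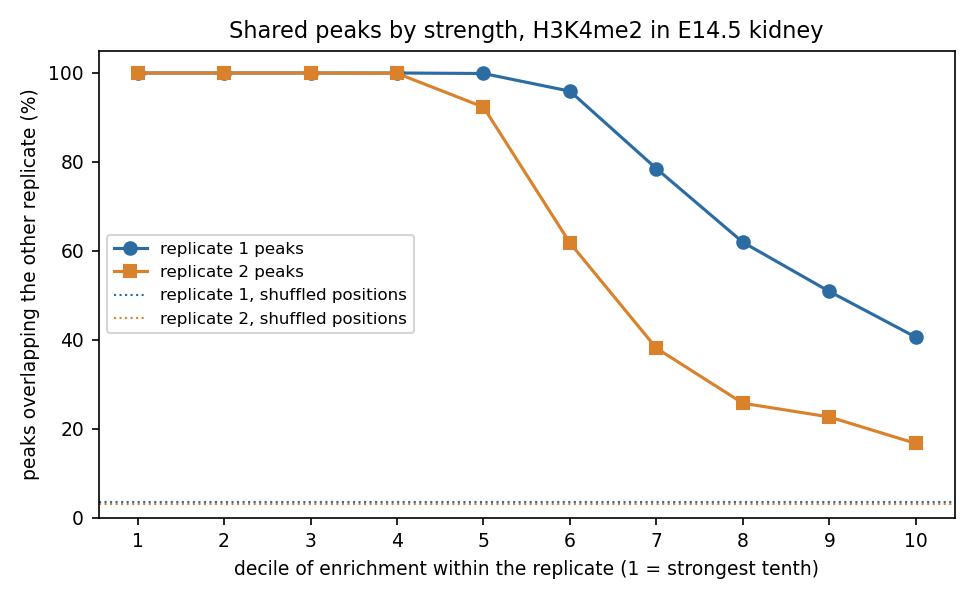
Percent of peaks that overlap a peak of the other replicate (vertical axis) by decile of the deposited −log10 p within each replicate (horizontal axis, 1 the strongest decile), with dotted lines for shuffled positions. The drawn axis label names enrichment, but the deciles were ranked by −log10 p. Replicate 1 falls from 100% to 40.6% and replicate 2 from 100% to 16.7%, and the shuffled values lie at 3.48% and 3.01%.

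The peaks marked in both replicates were ranked alike. Over 39285 overlapping pairs the enrichment values had a Spearman correlation of 0.73 and, on the log2 scale, a Pearson correlation of 0.74. With the 27413 pairs that overlapped by at least 50% of both peaks the Spearman correlation was 0.94. These are correlations across peaks, which are not independent replicates. Replicate 2 had the higher enrichment in 90.3% of pairs, with a median ratio of 1.62 over replicate 1. The 3 strongest peaks found in replicate 1 alone each had an enrichment of 6.195 and lay far from coding TSSs: inside Lims1, 22814 bp from its nearest TSS (chromosome 10, 58371264 to 58371854), 56414 bp from Kif13b and 194 bp from Mir124a-1, a neuronal microRNA gene (chromosome 14, 64590669 to 64591033), and 157061 bp from Hs2st1 (chromosome 3, 144412559 to 144413081). In replicate 2 alone the strongest were 31402 bp from Tcf7, a transcription factor of Wnt signalling (11.1), 23128 bp from Lemd1 (10.9) and 4156 bp from Il1f9, an interleukin gene (10.7). Both replicate lists named the same control files, so a fault in the controls would have been common to both.

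The replicated list kept the strong, wide part of the pooled list. All 33553 of its intervals were identical to pooled intervals, and they made up 77.9% of the pooled peaks. Their median enrichment was 12.4 and their median width 1030 bp, against 3.06 and 231 bp for the 9522 pooled peaks that were dropped. Of the dropped peaks, 6273 overlapped a peak of replicate 2 only, 1971 a peak of replicate 1 only, 1081 a peak of neither and 197 a peak of both. Of the replicated peaks, 93.1% overlapped a peak in both replicate lists, and 2318 did not. The share was 78.4% when each list was restricted to peaks with a −log10 q of at least 5.

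H3K4me2 was concentrated at promoters. The centres of 51.6% of the replicated peaks lay within 1 kb of a protein-coding TSS, which was 13.96 times the share of the genome in that class. Exons outside promoters held 4.14% of the centres (1.57 times their genome share), introns 19.7% (0.586 times) and intergenic sequence 24.5% (0.408 times). In the replicates' own lists the promoter share was 42.8% ± 4.12 (SD, n = 2) and the intergenic share 26.3% ± 1.52 (SD, n = 2). The highest enrichment, 61.4, belonged to a peak with 7.24 CpG dinucleotides per 100 bp inside Klhl31, a Kelch family gene, 19041 bp from its nearest coding TSS (chromosome 9, 77654837 to 77656244). It was followed by peaks 791 bp from the TSS of Rai1 (61.2), 343 bp from that of Trim67 (59.9) and 228 bp from that of Sptb, which encodes an erythrocyte-type spectrin (56.8). The fifth, 56.3, lay 181342 bp from Mkln1 and 2958 bp from the noncoding gene 2210408F21Rik (chromosome 6, 31215855 to 31218930).

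Genes of progenitors, early nephrons, ureteric bud, stroma and podocytes nearly all had a marked promoter, while genes of leukocytes, the germ line and several other tissues often did not. Of 21938 protein-coding genes, 14836 (67.6%) had a replicated peak within 1 kb of a TSS. 14767 genes had one in both replicates' own lists, 94 in replicate 1 only and 313 in replicate 2 only. All 20 nephron progenitor genes were marked, among them Pax2 and Wt1, transcription factors that kidney formation requires, with enrichments of 20.3 and 14.99 (adjusted exact p = 0.00128). So were all 20 early nephron genes (adjusted exact p = 0.00128), with Lhx1, a regulator of the renal vesicle, at 20.4, and all 18 podocyte genes (adjusted p = 0.00331), with Vegfa, a growth factor for vessels, at 33.5 and Nphs2, which encodes podocin of the slit diaphragm, at 10.5. Of the ureteric bud and collecting duct genes 21 of 22 were marked (adjusted exact p = 0.00544), with Gata3 at 31.2, and the exception was Aqp2, the water channel of the mature collecting duct. Of the stroma genes 19 of 20 were marked (adjusted exact p = 0.0116), with Pdgfra, a growth factor receptor, at 29.3, and Ren1, the renin gene, lacked a peak. Of the endothelial genes 17 of 18 were marked (adjusted exact p = 0.0175), with Fli1, an ETS factor, at 34.0, and Pecam1 lacked a replicated peak. Tek, Robo4 and Cdh5 counted as marked although replicate 1 alone had no peak within 1 kb of their TSSs. These p-values are from 2-sided Fisher's exact tests against all other coding genes with Benjamini-Hochberg adjustment over 20 lists. They compare genes within this tissue, and genes are not independent replicates.

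The other lists above the genome-wide share were the 23 ligands of the Wnt, Fgf, Bmp and Notch pathways, all marked (adjusted exact p = 7.06e-04), the 20 housekeeping genes, all marked (adjusted p = 0.00128), and the Hox genes, with 38 of 39 marked (adjusted p = 5.37e-05) and Hoxc12 as the exception. 9 of the ligands and 4 of the Hox genes also stood in a kidney list. Of the proximal tubule genes 8 of 18 were marked (adjusted exact p = 0.0586), including Lrp2, the endocytic receptor megalin, at 43.0 and Hnf1a at 10.7, while Cubn, which encodes its partner cubilin, had no covered base within 5 kb in the replicated list or in either replicate. Of the loop of Henle and distal tubule genes 8 of 14 were marked (adjusted exact p = 0.447), with Tfap2b at 9.44, while Cldn16, a tight junction gene, had none. Neither list passed the test, but the proximal tubule list did with a −log10 q of at least 5 (adjusted exact p = 0.0291) and with a window of 500 bp (adjusted exact p = 0.0318). Against random genes matched on promoter CpG count its expected share was 61.8%, and it did not pass (adjusted permutation p = 0.237).

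Lists of other tissues ranged from nearly unmarked to the genome-wide share. Of the leukocyte genes 2 of 16 were marked (adjusted exact p = 5.37e-05). These were the transcription factor genes Ikzf1 and Runx1, at 45.3 and 43.8. Of the pluripotency and germ line genes 2 of 14 were marked (adjusted exact p = 2.95e-04), Esrrb at 19.5 and Dazl at 14.7. Of the liver, pancreas, gut and lung genes 5 of 16 were marked (adjusted exact p = 0.00912), with Apoh at 41.8 and no peak at Alb, the albumin gene. Of the muscle, heart and skin genes 6 of 16 were marked (adjusted exact p = 0.0210), with Pmel at 20.6 and no peak at the keratin gene Krt14. Whether the peaks at Apoh, Pmel and the other marked genes belong to a neighbouring promoter was not checked. With replicate 2 alone neither of the latter 2 lists passed (adjusted exact p = 0.0719 and 0.141), and the muscle, heart and skin list did not pass with the pooled list (adjusted exact p = 0.0688). Only 3 of 1135 olfactory receptor genes (0.264%, exact binomial interval 0.0545% to 0.770%) had a peak. The erythroid list, with 7 of 16 marked, the neural crest and neuron list, with 10 of 14, the adrenal cortex and gonad list, with 7 of 14, and the brain and eye list, with 10 of 16, did not pass the test (adjusted exact p = 0.0727, 1, 0.193 and 0.831). In the neural crest and neuron list Phox2a, a regulator of autonomic neurons, was at 30.3, while Phox2b, Th, Dbh and Plp1 lacked a peak. In the erythroid list Tal1 was at 15.2 and Gata1 had none.

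CpG-rich promoters are often marked whatever the tissue, and matching random genes on promoter CpG count changed several of these calls. The count was taken at the gene 5' end, while a peak at any TSS marked a gene. The matching can therefore miss the CpG content of the promoter that was marked. The expected share became 92.2% for nephron progenitors (adjusted p = 0.436), 89.7% for ureteric bud (adjusted p = 0.675), 95.7% for early nephron (adjusted p = 0.936) and 87.6% for podocytes (adjusted p = 0.181), so these lists no longer passed the permutation test. Housekeeping and Hox genes (adjusted permutation p = 0.295 and 0.219) and, among the lists below, leukocytes (0.0811), liver, pancreas, gut and lung (0.219) and muscle, heart and skin (0.977) did not pass either. Every gene of the nephron progenitor, early nephron, podocyte and housekeeping lists was marked, so no higher share was possible. At these list sizes the matched test could not have passed for them. It therefore cannot tell whether CpG content accounts for their marking. The ureteric bud list was close to the same limit. Stroma stayed above its matched share of 68.6% (adjusted permutation p = 0.0044), endothelium above 69.5% (adjusted p = 0.0344) and the ligands above 85.5% (adjusted p = 0.0344). The endothelial share again counted Tek, Robo4 and Cdh5. Pluripotency and germ line genes stayed below 67.1% (adjusted permutation p = 4.0e-04) and olfactory receptors below 7.72% (adjusted p = 0.0020).

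**Figure D2:**
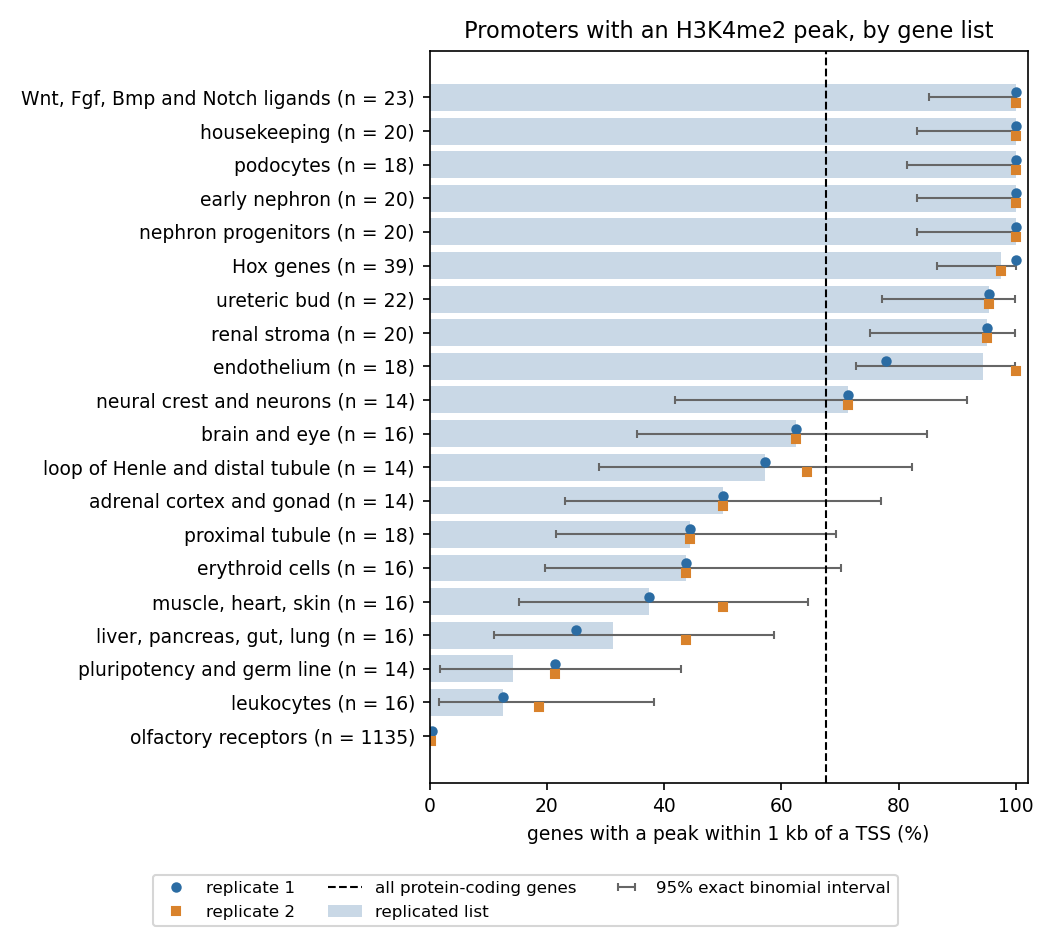
Percent of the genes of each list (vertical axis, n genes) with a peak within 1 kb of a TSS (horizontal axis); bars are the replicated list with 95% exact binomial intervals, points are the replicates' own lists, and the dashed line is all coding genes at 67.6%. The nephron progenitor, early nephron, podocyte, ureteric bud, stroma and endothelium lists lie at 94.4% or above in the replicated list, and the endothelial list is at 77.8% in replicate 1 and 100% in replicate 2.

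14 list members had a TSS peak in a single replicate. 4 of them were endothelial genes marked in replicate 2 only: Tek, an angiopoietin receptor (5.83), Robo4 (5.53), Cdh5, the endothelial cadherin (5.22), and Pecam1 (5.02). With replicate 1 alone 14 of 18 endothelial genes were marked and the list did not pass (adjusted p = 0.506, exact test), nor did it with a promoter window of 500 bp (adjusted p = 0.478, exact test). Sftpc, the lung surfactant gene, had the strongest such peak, at 33.2 in replicate 2. In replicate 1 it had 3139 marked bases within 5 kb and no peak within 1 kb. The other members marked in replicate 2 only were Zfp42 (5.14), Afp (4.35), Cd68 (3.95), Myf5 (3.56), Nkx2-5 (3.56), Tmem52b (3.46) and Vil1 (2.71). Mael (3.26) and Hoxc12 (3.25) were marked in replicate 1 only.

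Hox genes, several lists of embryonic kidney cells, the ligands and housekeeping genes were marked over wider stretches around their promoters than marked genes in general. Among marked genes, breadth was the number of bases covered within 5 kb of a TSS, and it averaged 2634 bp. Hox genes averaged 7559 bp, nephron progenitor genes 6601 bp, early nephron genes 5519 bp, stroma genes 5014 bp, ureteric bud genes 4400 bp and the ligands 4155 bp, each with adjusted p = 6.67e-05 from a raw p of 2.0e-05, the smallest the permutations can give. Housekeeping genes averaged 4009 bp (adjusted permutation p = 2.29e-04) and podocyte genes 3919 bp (adjusted p = 0.00142). Neighbouring Hox genes share marked bases and are not independent. All 8 lists also passed against marked genes matched on promoter CpG count. Breadth was the largest value over the TSSs of a gene, so genes with more TSSs had more chances of a high value. Bases marked at close neighbouring genes were counted too. The test was not matched on the number of TSSs or on gene density. Pax2 (chromosome 19, 44756045 to 44837871) had 9893 covered bases, with 9195 in replicate 1 and 9954 in replicate 2. Wt1 (chromosome 2, 105126529 to 105173616) had 9893, with 9664 and 9893. In the stroma list Meis1 and Meis2, homeobox genes, were covered over all 10001 bases, and Pdgfra over 9496. In the early nephron list Lhx1 had 9326, Irx3 8503 and Pou3f3 8245, and in the ureteric bud list Gata3 had 9813 and Emx2, a homeobox gene, 8870. Widths were small at Nphs2 (595 bp), Elf5 (307 bp), Lum (705 bp) and Crym (1694 bp).

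Brain and eye genes and olfactory receptor genes had lower breadth than random marked genes. The 10 marked brain and eye genes averaged 1691 bp (adjusted p = 0.0189, permutation test), with Dlx2 at 3439 bp. The 3 marked olfactory receptor genes averaged 640 bp (adjusted p = 3.0e-04, permutation test). The brain and eye call was lost with windows of 10 kb on either side (adjusted permutation p = 0.158), against genes of matched CpG count (adjusted p = 0.100) and with replicate 2 alone (adjusted p = 0.0690). The 6 marked muscle, heart and skin genes averaged 1619 bp (adjusted permutation p = 0.0550), and the 2 marked pluripotency and germ line genes 1208 bp (adjusted p = 0.0989). Both passed in each replicate's own list by the same permutation test, with adjusted p between 0.00604 and 0.0444. Those lists can hold further weakly marked genes, such as Mael in replicate 1 and Zfp42 in replicate 2. The pluripotency and germ line mean was 827 bp in replicate 1 and 888 bp in replicate 2. Against genes of matched CpG count neither list passed (adjusted permutation p = 0.357 and 0.162). The remaining lists did not pass: proximal tubule at 1997 bp, loop of Henle and distal tubule at 2077 bp, endothelium at 2730 bp, leukocytes at 3322 bp, erythroid cells at 2744 bp, neural crest and neurons at 1926 bp, adrenal cortex and gonad at 1831 bp, and liver, pancreas, gut and lung at 2382 bp.

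**Figure D3:**
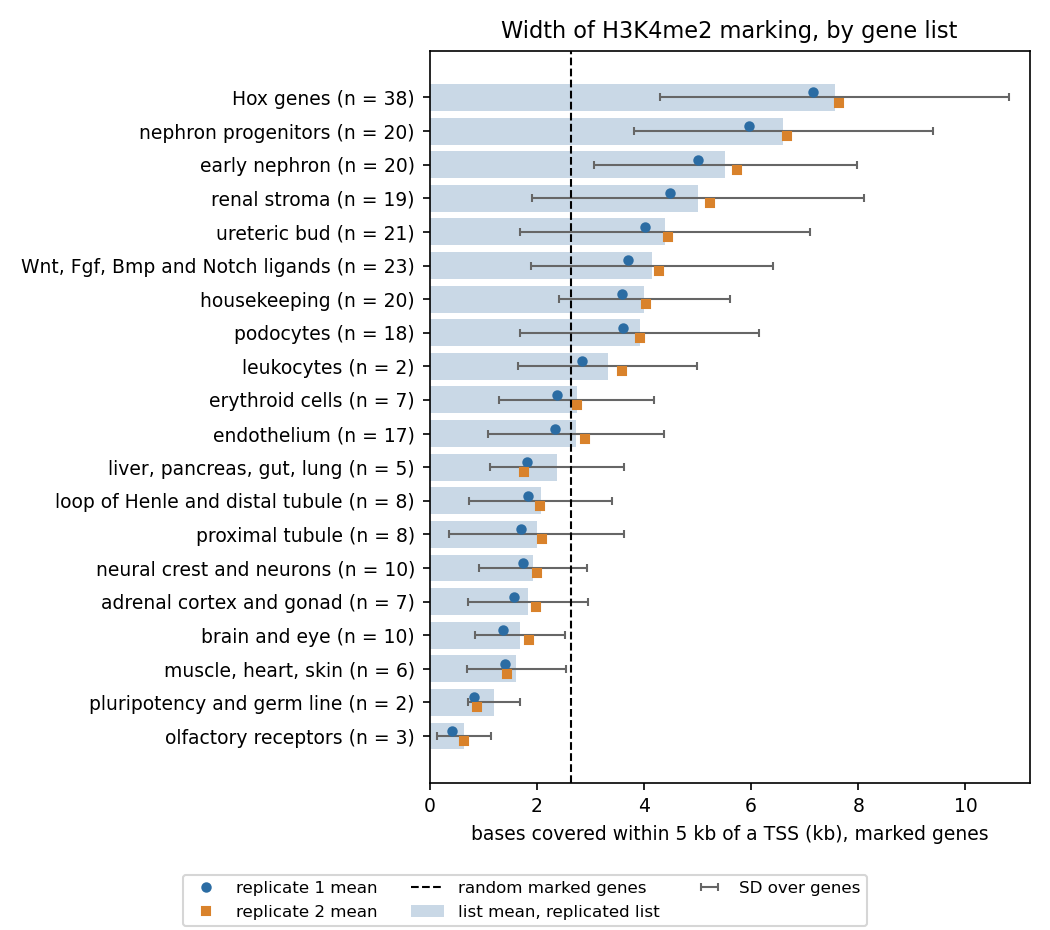
Mean number of bases covered within 5 kb of a TSS (horizontal axis, kb) for the marked genes of each list (vertical axis, n marked genes); bars are the replicated list with the SD over genes, points are the replicates' own means and the dashed line is the mean of all marked genes. Hox genes (7559 bp) and nephron progenitor genes (6601 bp) are the widest, against 2634 bp for all marked genes.

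The widest domains of H3K4me2 lay on the Hox clusters, whose genes pattern the body axis. With peaks 1 kb apart or less joined, there were 766 domains of at least 5 kb. The widest, 58.8 kb, held the TSSs of Hoxb3 to Hoxb8 (chromosome 11, 96276609 to 96335420). The next held Hoxa3, Hoxa5 to Hoxa7 and Hoxa9 to Hoxa11 over 50.4 kb (chromosome 6, 52199994 to 52250367), and Hoxd genes from Hoxd3 to Hoxd12 over 42.4 kb (chromosome 2, 74674480 to 74716914). The fourth held Hoxc5, Hoxc9 and Hoxc10 over 26.5 kb (chromosome 15, 102958872 to 102985419). Then came Nr2f2, an orphan nuclear receptor gene (26.01 kb, chromosome 7, 70345405 to 70371412), Hoxa1 and Hoxa2 (24.8 kb), Meis2 (23.0 kb, chromosome 2, 116053681 to 116076666), Gata3 (22.6 kb), Hoxd3 and Hoxd4 (20.3 kb) and Pax2 (18.5 kb, chromosome 19, 44745706 to 44764236). Replicate 1 peaks covered between 81.8% and 97.7% of the bases of each of these 10 domains, and replicate 2 peaks between 92.5% and 99.3%. Genes with a TSS in a domain of at least 5 kb made up 5.91% of all marked genes, against 28 of 38 Hox genes (adjusted p = 1.44e-25), 13 of 20 nephron progenitor genes (adjusted p = 5.2e-11) and 11 of 20 early nephron genes (adjusted p = 1.98e-08) by Fisher's exact test. The share was also higher for the ligands (9 of 23, adjusted exact p = 1.63e-05), stroma (8 of 19, 2.43e-05), ureteric bud (8 of 21, 4.91e-05), podocytes (6 of 18, 0.0012) and housekeeping genes (6 of 20, 0.00198), and the other 12 lists did not pass. Neighbouring Hox genes share domains, as Hoxb3 to Hoxb8 do, so they are not independent and the Hox p-value is too small. Hoxa11, Hoxc10 and Hoxd11 of the nephron progenitor list lie in these domains too. This test of domains was added after the ranking, with Hox clusters at its top, was seen.

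Coverage of the Hox genes differed by position in the clusters. The share was taken at the TSS of each gene with the largest coverage. Within 1 kb of that TSS, every base was covered at Hoxa1 to Hoxa11 and at Hoxb3 to Hoxb9. The covered share was 83.3% at Hoxa13, 21.04% at Hoxb13, 54.2% at Hoxc13 and 68.1% at Hoxd13, and Hoxc12 had no covered base there. At the other end of the clusters it was 80.3% at Hoxb1 and 97.4% at Hoxd1.

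**Figure D4:**
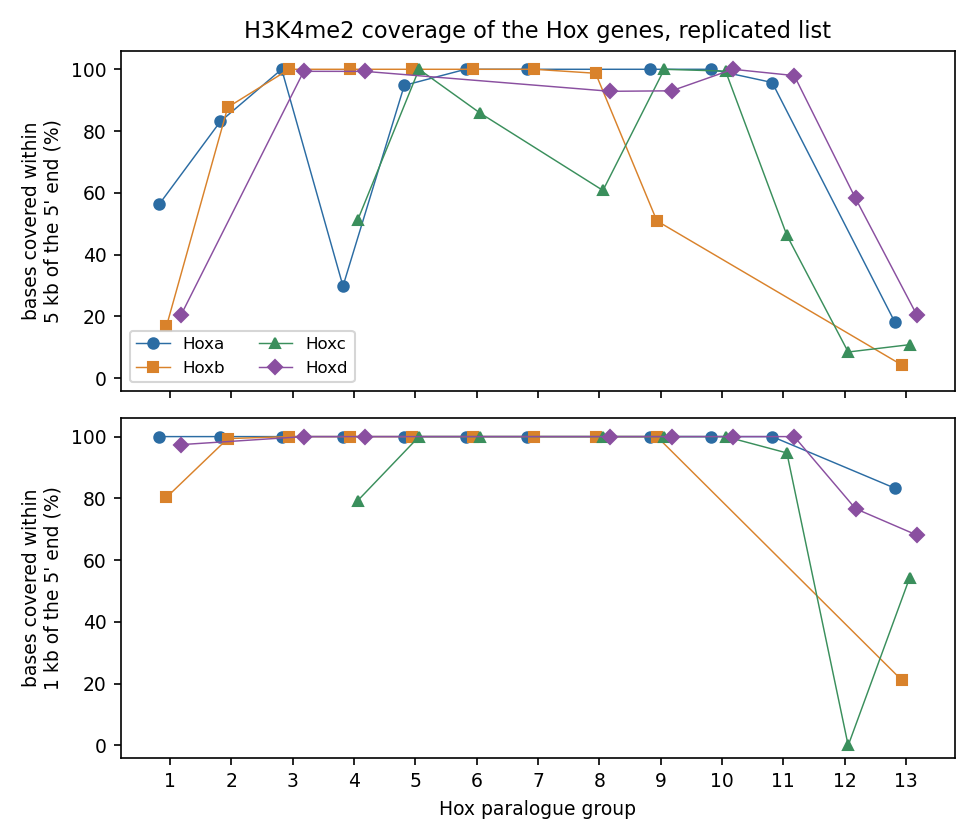
Percent of bases covered by replicated peaks within 5 kb (upper panel) and 1 kb (lower panel) of a TSS of each Hox gene, by paralogue group (horizontal axis), with a line for each of the Hoxa, Hoxb, Hoxc and Hoxd clusters. The TSS with the largest coverage was used, although the drawn axis labels name the 5' end. In the lower panel groups 3 to 11 are at or near 100%, with Hoxc4 at 79.3% the lowest, and Hoxc12 is at 0% and Hoxb13 at 21.04%.

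Distal peaks, which lay over 2.5 kb from every coding TSS, were most numerous around Hox genes and genes of nephron progenitors and the ureteric bud. There were 13244 such peaks, and a coding gene had on average 0.931 of them within 50 kb. Hox genes had 5.87 (adjusted p = 1.33e-04), nephron progenitor genes 3.15 (adjusted p = 1.33e-04), ureteric bud genes 3.05 (adjusted p = 1.33e-04), stroma genes 2.45 (adjusted p = 0.00384), endothelial genes 2.06 (adjusted p = 0.0295), early nephron genes 2.00 (adjusted p = 0.0295), brain and eye genes 2.00 (adjusted p = 0.0492) and the ligands 1.96 (adjusted p = 0.0278), all by permutation. Neighbouring Hox genes share distal peaks, so their counts are not independent. Counts were higher in the replicates' own lists, which hold more peaks: Hox genes had 9.31 in replicate 1 and 12.1 in replicate 2, nephron progenitor genes 5.15 and 6.10, and all coding genes 1.36 and 1.65. Pou3f3 had 10 replicated distal peaks (21 and 13 in replicates 1 and 2), Meis2 had 9 (17 and 14) and Pax2 had 7 (13 and 11). Olfactory receptor genes had 0.0749 (adjusted permutation p = 0.0010). The brain and eye call was lost against genes matched on gene density (adjusted permutation p = 0.0518), with the pooled list (adjusted p = 0.186) and with each replicate alone (adjusted p = 0.175 and 0.313). The endothelial call was lost with replicate 1 alone (adjusted permutation p = 0.151) and with a −log10 q of at least 5 (adjusted p = 0.0549), and the early nephron call with a limit of 100 kb (adjusted p = 0.107).

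The other lists did not pass the test of distal peaks: housekeeping genes had 1.80 (adjusted permutation p = 0.0636), podocyte genes 1.67 (adjusted p = 0.138), erythroid genes 1.63, adrenal cortex and gonad genes 1.43, proximal tubule genes 1.22, leukocyte genes 1.13, liver, pancreas, gut and lung genes 1.13, neural crest and neuron genes 1.07, loop of Henle and distal tubule genes 0.929, pluripotency and germ line genes 0.786, and muscle, heart and skin genes 0.750. The podocyte list passed with replicate 2 alone (adjusted permutation p = 0.00566) and with the pooled list (adjusted permutation p = 0.0380), and the housekeeping list with a limit of 100 kb (adjusted permutation p = 0.0195). The genes with the most distal peaks were Ahdc1 (19, chromosome 4, 133011260 to 133078110), Btn1a1, a milk fat butyrophilin (17), Foxp1, a forkhead factor (16), Gse1 (16), Hoxc5 (16), BC107364 (15), Btn2a2 (15), Zfp184 (15), Zfhx3 (14) and Abt1 (13). Peaks were counted around every TSS, so a gene with widely spaced TSSs was searched over more sequence. Neither this ranking nor the list tests adjusted for that.

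Distal peaks were rich in motifs of several transcription factor families. Against flanking sequence matched on GC content, CTCF motifs, bound by the insulator protein, were 3.77 times as dense (95% bootstrap interval 3.10 to 4.71), and 2.46 times (1.95 to 3.21) with replicate 2 alone. ETS motifs were 1.93 times as dense (1.52 to 2.58), forkhead (FOX) motifs 1.80 times (1.69 to 1.91), the homeodomain core TAATTA 1.74 times (1.62 to 1.86), motifs of the progenitor regulators Six1 and Six2 1.63 times (1.32 to 1.96) and the motif of Hox groups 9 to 13 1.57 times (1.41 to 1.75). MEF2 motifs were at 1.81 (1.36 to 2.41), OCT at 1.76 (1.5 to 2.03), CRX/OTX at 1.35 (1.06 to 1.66), TCF/LEF, the site of Wnt signalling, at 1.18 (1.08 to 1.29), SRF at 1.15 (1.03 to 1.28) and TEAD at 1.11 (1.03 to 1.19). NFI motifs were at 4.58 (2.38 to 12.5) with 21 sites. The interval included 1 for GATA (1.05), AP-1 (0.951), TFAP2 (1.07), REST (0.893) and HNF1 (3.63, with 9 sites), and the PAX2/8 motif had 2 sites, too few for an interval. Without GC matching the forkhead ratio was 1.08, NFI 2.94, HNF1 1.68, the homeodomain core 0.847, MEF2 0.956, OCT 0.969, TCF/LEF 0.948, SRF 0.849, GATA 0.808 and the Hox motif 1.03, while CTCF was at 4.77, ETS at 2.998 and TFAP2 at 2.38 (2.24 to 2.55). Several calls depended on the setting. Beyond 10 kb from every TSS the interval included 1 for TEAD (0.998 to 1.21), SRF (0.936 to 1.28) and CRX/OTX (0.957 to 1.85). It also did for SRF (0.925 to 1.21) and CRX/OTX (0.853 to 1.69) with replicate 1 alone, and for TCF/LEF (0.98 to 1.23) and CRX/OTX (0.940, 0.612 to 1.42) with replicate 2 alone. In turn the interval lay above 1 for TFAP2 with replicate 1 alone (1.03 to 1.22) and, with replicate 2 alone, for TFAP2 (1.05 to 1.24), GATA (1.06 to 1.22) and HNF1 (1.40 to 12.8), and for HNF1 beyond 10 kb (8 sites). For AP-1 it lay below 1 without GC matching (0.861 to 0.986), with replicate 2 alone (0.831 to 0.994) and beyond 10 kb (0.853 to 0.999).

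**Figure D5:**
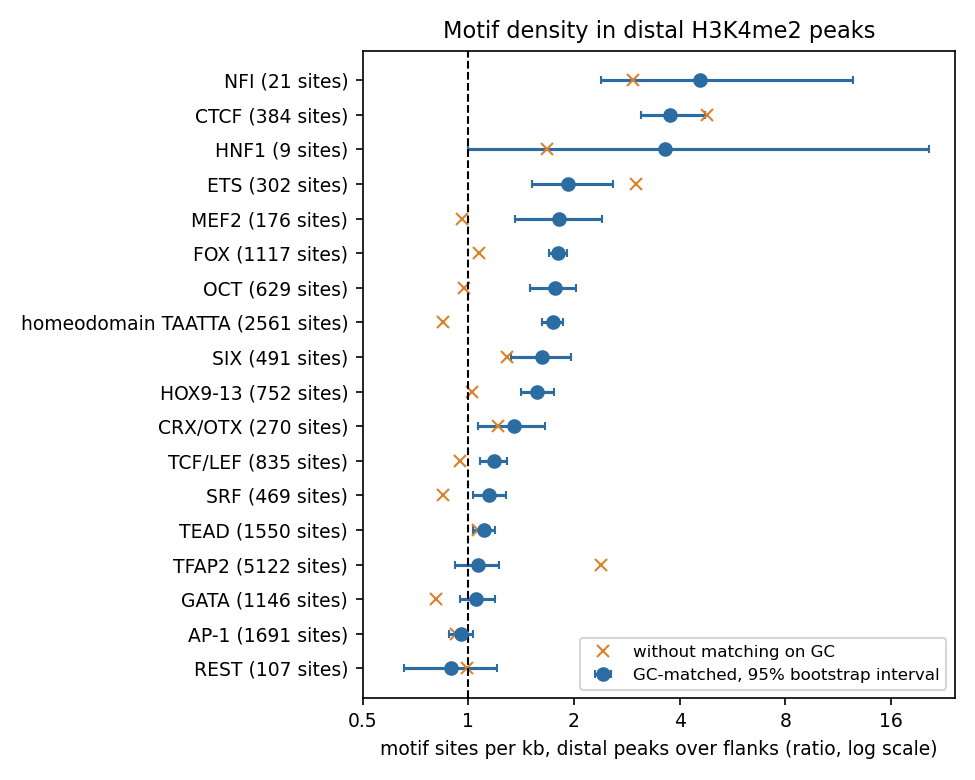
Ratio of motif sites per kb in distal peaks over flanking sequence (horizontal axis, log scale) for each motif with an interval (vertical axis, number of sites in the peaks); points are GC-matched ratios with 95% bootstrap intervals over chromosomes and crosses are ratios without matching. CTCF lies at 3.77 and 4.77 by these measures, and the homeodomain core at 1.74 and 0.847.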

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

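All of these alternatives were planned before the data were examined. Of 566 values under alternatives, 468 kept their direction and side of the threshold or stayed within a tolerance, 40 moved beyond it, 20 passed a threshold that the reported value did not, 31 no longer passed and 7 changed direction. The tolerance was the counting interval for shares of peaks, the SD of the replicates for genomic classes, a fixed fold for counts and equality after rounding for correlations. The cause was not tested except where stated. The share of replicate 1 peaks overlapping replicate 2 (82.8%) became 73.5% and 62.2% at 25% and 50% reciprocal overlap, 97.9% with a −log10 q of at least 5, 80.6% with equal numbers of peaks, 81.6% with peaks joined and 82.4% without X, Y and unplaced sequence; that of replicate 2 (65.7%) became 61.9%, 52.9%, 78.9%, 74.1% and 72.5% in the first 5 of these. The Spearman correlation was 0.94 at 50% reciprocal overlap and 0.74 with −log10 p. With the q limit 97.49% of pooled peaks were retained and 78.4% of replicated peaks were in both lists, and at 50% reciprocal overlap 80.5%. The promoter share (51.6%) was 43.2% in the pooled list, 37.3% and 60.5% with windows of 500 bp and 2.5 kb, 58.7% of bases, and 39.9% to 45.7% with 1 replicate; the intergenic share (24.5%) was 27.1% in the pooled list and with 500 bp, 16.6% of bases and 25.2% to 27.4% with 1 replicate. Of the lists by promoter marking (9 above, 5 below), matching on CpG left 3 above and 2 below, and 3 to 5 were below with 1 replicate. For breadth, 8 lists were above in every setting; 2 were below in the main setting, 4 with the pooled list, 1 with 10 kb windows, 1 with CpG matching and 3 to 4 with 1 replicate. Domains of at least 5 kb numbered 358 without joining and 1449 when joined within 3 kb (766 at 1 kb), and 5 of the 10 widest stayed among the 10 widest without joining. Motifs with an interval above 1 fell from 13 to 8 without GC matching, where 4 had an interval below 1; the numbers below 1 were 1 beyond 10 kb from every TSS and 0 to 1 with 1 replicate. Ratios that crossed 1 without GC matching were the homeodomain core (0.847), GATA (0.808), MEF2 (0.956), OCT (0.969), SRF (0.849) and TCF/LEF (0.948), since this setting compares peaks with flanks of other base composition; CRX/OTX ranged from 0.940 to 1.20 with 1 replicate. Without read counts, absence of a peak cannot be told from too few reads at weakly marked regions.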

Other observations

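The gene families, noncoding genes, chromosomes and all 6 tests of explanations below were chosen after the main results were seen. Among 22 families defined by gene symbol, cilium genes of the intraflagellar transport, Bbs, nephrocystin and polycystin groups were marked in 28 of 28 cases (Fisher's exact test adjusted over the families, p = 5.37e-05). Zinc finger genes named Zfp were marked in 344 of 394 cases (adjusted exact p = 8.17e-19), ribosomal protein genes in 78 of 88 (adjusted p = 1.67e-05), collagens in 40 of 45 (adjusted p = 0.00219), Fox genes in 38 of 44 (adjusted p = 0.00937), Sox genes in 18 of 19 (adjusted p = 0.0171) and Slc transporters in 283 of 371 (adjusted p = 5.32e-04). Marks were less frequent than among all other coding genes at vomeronasal receptors (1 of 331, adjusted exact p = 5.86e-161), defensins (1 of 64, adjusted p = 5.53e-29), keratins (12 of 53, adjusted p = 9.69e-11), cytochrome P450 genes (26 of 100, adjusted p = 1.34e-16), clustered protocadherins (15 of 57, adjusted p = 6.93e-10), interleukins (10 of 37, adjusted p = 1.53e-06), claudins (13 of 33, adjusted p = 0.00206) and the Slc22 and Slco transporters of organic anions and cations (14 of 39, adjusted p = 1.14e-04). The Tbx (9 of 13), Irx (6 of 6), sine oculis homeobox (6 of 6), Gata (5 of 6), Pax (8 of 9), Lhx (8 of 8) and aquaporin (6 of 11) families did not pass. All Irx, sine oculis homeobox and Lhx genes were marked, so families of that size could not pass (unadjusted exact p = 0.187, 0.187 and 0.0606). None of these was matched on promoter CpG count.

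For noncoding genes the measure was a replicated peak at the gene 5' end, not at any TSS, and no test against coding genes was made. A replicated peak lay within 1 kb of the 5' end of 93.7% of 190 bidirectional promoter lncRNAs, of which 1 lay over 2.5 kb from a coding TSS and was not marked, and of 17.6% of 5854 lincRNAs, 12.02% of those over 2.5 kb from a coding TSS. Wide marking far from coding TSSs was found at 8430419K02Rik (8835 bp covered within 5 kb), at Neat1, a paraspeckle RNA (7715 bp), at Malat1, a nuclear speckle RNA (7165 bp), and at the microRNA genes Mir322 (7087 bp) and Mir125b-1 (7057 bp). Of the distal peaks 10.03% lay within 1 kb of a noncoding TSS, against 2.996% of positions moved by 20 kb. Chromosome 11 had the most replicated peaks per Mb (21.7), X had 5.47 with 51.8% of its coding genes marked, and Y had 8 peaks in all.

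Distal peaks near Btn1a1, Btn2a2, Abt1 and Zfp184 on chromosome 13 (21896648 to 23527326, 38 peaks) and BC107364 on chromosome 3 (96404344 to 96501459, 15 peaks) are far denser than around most genes. If the peaks consisted largely of repeated sequence, many of their 50-base words would occur more than once in the genome. Of these words 2.26% did, against 0.390% in 300 other distal peaks, and the limit set in advance was 10%. The median width of the peaks near each gene was 761 to 1587 bp, so a short repeated stretch would also give a low share. The test therefore cannot exclude reads gathered at such stretches. A candidate explanation is that they are promoters of transfer RNA genes, which the coding annotation leaves out: 81.1% of these 53 peaks lay within 1 kb of a tRNA gene, against 0.978% of the 13191 other distal peaks. All 15 peaks at Zfp184 and 8 of 15 at BC107364 did, and none near Ahdc1, Foxp1, Gse1, Hoxc5 or Zfhx3.

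The Hox genes of groups 12 and 13 had fewer marked bases within 5 kb of a TSS than those of groups 1 to 11, with 20.1% ± 19.6 (SD over 6 genes) against 83.6% ± 25.8 (SD over 33 genes; exact permutation p = 4.35e-05), although windows of neighbouring genes overlap, so genes are not independent. For each gene the TSS with the largest coverage was used, so genes with more TSSs had more chances of a high share. Low coverage at 5 kb was shared by Hoxb1 (16.8%), Hoxd1 (20.5%) and Hoxa4 (29.8%), and Hoxd12 was at 58.2%. More Hox promoters inside the windows of the other groups were predicted to leave no gap close to the TSS. Within 1 kb the covered share was still lower (difference −47.97 percentage points, exact permutation p = 2.45e-06). However, neighbouring Hox genes can share 1 wide peak, and Hoxb3 to Hoxb8 all have an enrichment of 35.4. Such a peak also fills the 1 kb windows, so this test cannot exclude an effect of neighbouring Hox promoters. Fewer CpG dinucleotides would give a lower CpG count, but the count within 500 bp of the gene 5' end was higher by 26.2 (78.7 against 52.5, exact permutation p = 0.0401). The gene 5' end need not be the TSS with the largest coverage, so the CpG content at that TSS was not tested. Lower marking of these genes in this tissue remains a hypothesis, found and tested on the same data, and no biological explanation was tested.

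4 of 18 endothelial genes, Pecam1, Cdh5, Tek and Robo4, had a TSS peak in replicate 2 and none in replicate 1. Random genes matched on replicate 2 enrichment lacked a replicate 1 peak in 3.12 cases on average (central 95% of lists 1 to 6, permutation p = 0.766), so weaker enrichment in replicate 1 may account for the pattern. More endothelial cells in replicate 2 would raise the ratio at the 14 genes marked in both, but the mean log2 ratio differed from matched lists by −0.13 (0.55 against 0.68, permutation adjusted p = 0.739). This value did not pass the threshold in either direction, so a difference in cell content stays open.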
